A study of Homo sapiens with 62 samples.

How the data were processed

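Expression values were the deposited processed values of the series, one table of 54675 probe sets for 62 arrays of the Affymetrix U133 Plus 2.0 type. Per the submitters' processing notes the values were made with Partek, and no step before the deposited table was repeated. The deposited values were on the log2 scale, from 2.19 to 14.8, and were used without further transformation. The array medians lay between 5.32 and 5.44, and the median correlation of each array with the others lay between 0.989 and 0.995.

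Of 54613 probe sets that are not controls, 41091 carried 1 gene symbol, 1801 carried several and 11721 carried none. The symbols of 41037 were looked up through the Entrez identifier, which changed none, and 54 were kept as given by the platform. The annotation of the platform can be old. For 10523 genes with several probe sets, the probe set with the highest mean was used, which gave 19775 genes. Probe sets that list several genes were left out, so TNFSF12 has no value.

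Tumours carry a treatment, a time and an array set read from the titles. The 2 tumours measured again in a further array set were averaged with their first arrays, so that 60 tumours were tested. The standard deviation of the difference between first and repeat array was 0.134 and 0.202, beside a median of 0.214 over all pairs of arrays. For the tumour with 0.202 the first array ranked 3 in nearness to the repeat among 61 arrays.

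Differences were tested with limma 3.58.1 in R 4.3.3, with 12 groups and the array set in the model and 47 residual degrees of freedom. The p-values were moderated and adjusted by Benjamini and Hochberg over all genes, and an adjusted p below 0.05 counted as past the threshold. Each antibody was compared with vehicle and with the other antibody at each time and averaged over the 4 times, vehicle tumours of 8, 24 and 72 h were compared with those of 4 h, and an interaction test asked whether the effect differed between times. Tumours are the replicates, 5 in each group, and the p-values measure the spread between these tumours, all from 1 cell line.

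Genes were named in the text by a rule. TNFRSF12A, the gene of the TWEAK receptor, and VEGFA were always read. Next came up to 10 of the largest rises and falls among genes past the threshold with the same sign in both array sets. Then came the 3 smallest p where none passed, and up to 4 members of a list with the smallest p. The 26 gene lists were written before the data were examined. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. The p-values of the lists were adjusted over 390 treatment tests and over 78 time tests. With the preset correlation 87 and 26 of these passed, none did with an estimated correlation, and 1 and 3 did with fry. A count adjusted over the list alone adjusts the p-values of the members of a list among themselves.

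RNA quality was read as the mean over GAPDH and ACTB of the 3' minus the 5' control probe set. Means of marker lists stood for host and stromal cells. These were compared between arms by 99999 permutations of tumours, or exactly over 252 splits within a time. Chance was examined with 100 splits of the same tumours for each comparison, the real split included.

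The limma test was tried on simulated values with 200 changed genes in 20 draws. The comparisons tried were TW212 against vehicle at 1 time and averaged over time. With 5 tumours per side the limma test recovered 21.0% of changes of 0.25, 88.3% of changes of 0.5 and 99.9% of changes of 1 on the log2 scale. With 20 tumours per side it recovered 91.3%, 99.7% and 100%. The median share of false calls was 2.10% and 1.76%, the highest was 13.0% and 11.0%, and no call had the wrong sign. These shares belong to draws with 200 changed genes. The trial gave no share for fewer changed genes or for RNA quality that differs between the arms. Gene lists, interaction tests, permutations and added model terms were not part of the trial.

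Alternatives to these choices covered the array set term, the repeat arrays, normalization, the choice of probe sets and genes, the variance model, terms for RNA quality and leukocyte markers, and each tumour left out. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Raw array scans were not analysed here, and no measurement of protein, vessel density or tumour size was analysed here.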

Results

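ACHN, an established cell line from a human renal adenocarcinoma, was grown as subcutaneous tumours in nude mice, and RNA was measured on human expression arrays. The mice received TW212, an antibody against TWEAK, or B20.4.1, an antibody against VEGF, or vehicle. TWEAK is a cytokine of the TNF family whose receptor TNFRSF12A signals to NF-kB, and VEGF drives the growth of blood vessels. Tumours were taken after 4, 8, 24 or 72 h, which gave 12 groups of 5 tumours and 60 tumours in all. The labels hold the 72 h tumours, although the design text of the series names only the shorter times. The titles placed 3 tumours of every group in array set 1 and 2 in array set 2, and 2 tumours were also measured again in a further set. Tests covered 19775 genes, and the number of arrays limits the precision of every value.

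The largest axis of variation among the tumours followed RNA quality. The first principal component held 20.1% of the variance, and the difference between the 3' and 5' control signals of GAPDH and ACTB, which is larger where RNA is shorter, explained 86.4% of it. This difference was 0.84 ± 0.34 on the log2 scale in the TW212 tumours and 0.61 ± 0.24 in the vehicle tumours (SD, n = 20 each, permutation p = 0.0135, adjusted p = 0.0497 over 24 tests). In the B20.4.1 tumours it was 0.65 ± 0.24. At 24 h it was 0.41 ± 0.06 with vehicle and 0.77 ± 0.24 with B20.4.1 (n = 5 each, exact permutation p = 0.00794, adjusted p = 0.0873). The second component held 12.8% of the variance, and the mean level of leukocyte genes, which lay under the median of all probe sets, explained 84.2% of it. Of the marker lists only this one was set against the components, so the second component is not shown to be an axis of leukocytes. Array set explained 56.7% of the third.

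**Figure D1:**
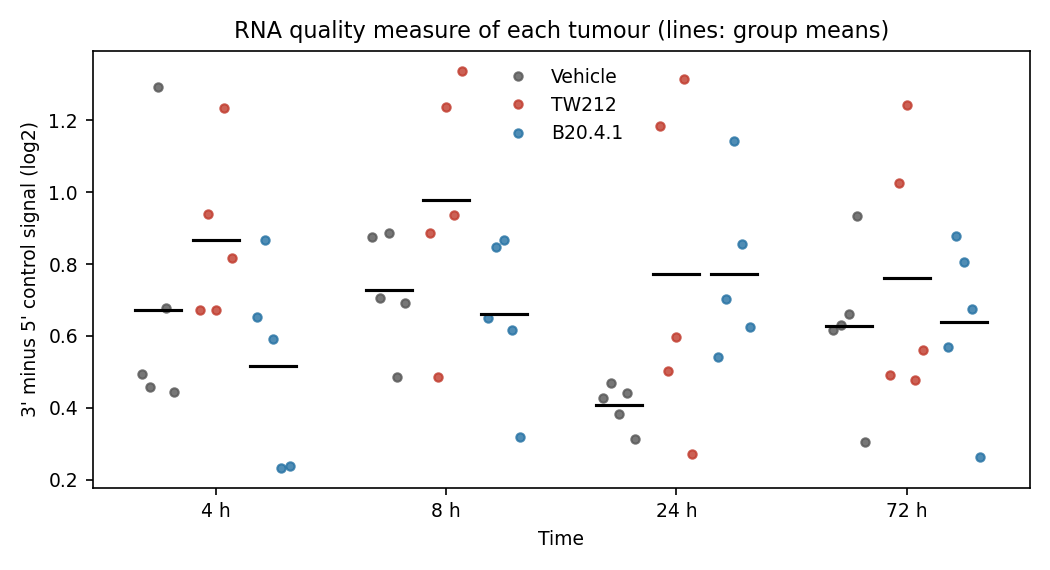
RNA quality of each of the 60 tumours, as the 3' minus 5' control signal (log2, vertical axis), by time (horizontal axis) and treatment, with a line at each group mean. The vehicle tumours of 24 h sit at a mean of 0.41 and the TW212 and B20.4.1 tumours of 24 h at means of 0.77.

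The first question was whether the antibodies changed the RNA of the TWEAK receptor and of VEGFA. TNFRSF12A, the TWEAK receptor, differed from vehicle by 0.02 ± 0.03 on the log2 scale with TW212 averaged over time (SE, n = 20 per arm, adjusted p = 0.846) and by 0.05 ± 0.03 with B20.4.1 (adjusted p = 0.496). VEGFA differed by -0.06 ± 0.06 with TW212 (adjusted p = 0.644) and by -0.08 ± 0.06 with B20.4.1 (adjusted p = 0.556). Neither gene passed the threshold at any time. TNFSF12, the gene of TWEAK itself, had only probe sets that list several genes and was not read. Of the 12 measured genes of the TWEAK receptor pathway, none passed over all genes or adjusted over the list alone with TW212 averaged over time, and their median was 0.00, while camera pointed down (camera adjusted p = 0.950).

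Averaged over the 4 times, SFRP1 changed more with TW212 than any other gene that passed. SFRP1, a secreted antagonist of Wnt signals, fell by 0.60 ± 0.10 on the log2 scale, or 1.51-fold (SE, n = 20 tumours per arm, adjusted p = 0.00406), and was lower in 18 of the 20 treated tumours than the vehicle mean. IGF1, a growth factor, fell by 0.37 ± 0.08. The matrix-degrading enzyme MMP13 fell by 0.24 ± 0.05 at a low level (4.29 against 4.53, with a median of 5.37 over all probe sets), and the cytokine IL6 fell by 0.24 ± 0.06 (adjusted p = 0.0499). CDH11, an adhesion molecule of mesenchymal cells, fell by 0.31 ± 0.07, and the lipid receptor S1PR3 fell by 0.26 ± 0.05. CCNA1, a cyclin, fell by 0.38 ± 0.08, while SERPINI1, also of low level, PRSS23 and NFE2L3 fell by 0.28 ± 0.06, 0.22 ± 0.05 and 0.22 ± 0.05. Among the genes that rose were APOLD1, an early response gene of blood vessel cells, at 0.34 ± 0.07, KANSL1L at 0.33 ± 0.06, and the mucin MUC1 at 0.29 ± 0.06. CCNF, a cyclin that marks proteins for degradation, rose by 0.24 ± 0.05, as did the RNA-binding protein gene DND1, which rose by 0.25 ± 0.05. SS18L1 (0.27 ± 0.06), PAXIP1-AS2 (0.25 ± 0.05), RELN (0.23 ± 0.06), SLC26A2 (0.23 ± 0.05) and EPB41L4A (0.22 ± 0.05) were the other named rises. In all, 43 of 19775 genes passed, 27 higher and 16 lower, each with the same sign within array set 1 and array set 2. The calls rest on both array sets together, which favours the same sign in each, here and in every comparison below. In array set 1 alone and in array set 2 alone 0 genes passed. SFRP1 was at -0.60 in set 1 and -0.59 in set 2, and other probe sets of SFRP1 gave -0.13, -0.17 and -0.02. Another probe set pointed the other way for KANSL1L, PAXIP1-AS2, EPB41L4A, IGF1, CDH11 and PRSS23. With the RNA measure in the model 4 genes passed, and without the 9 tumours above 1 in that measure none did. With a single tumour left out the count ran from 5 to 1298.

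**Figure D2:**
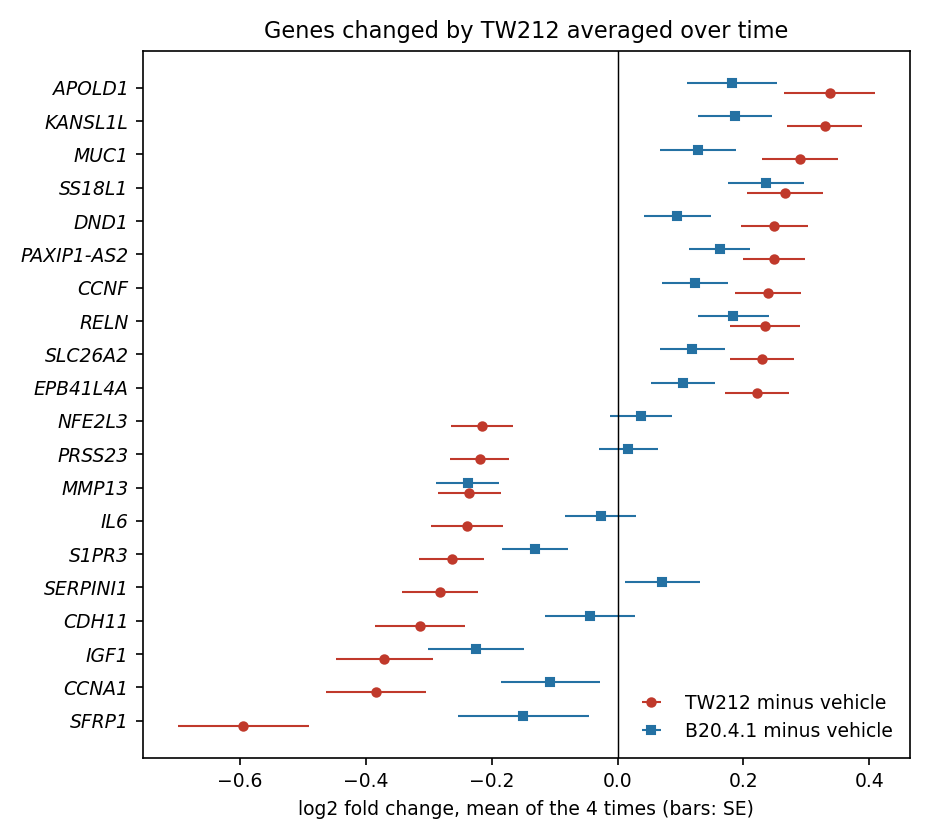
Log2 fold changes against vehicle, averaged over the 4 times (horizontal axis, bars SE), of the named genes that TW212 changed (vertical axis), with the B20.4.1 change of the same genes. SFRP1 stands at -0.60 with TW212 and at -0.15 with B20.4.1.

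Extracellular matrix and invasion genes were lower with TW212 averaged over time. Of 33 measured members 28 were lower, with a median of -0.07, and MMP13, a gene of low level, fell over all genes, while adjusted over the list alone 9 fell and 2 rose (camera adjusted p = 4.79e-05). With an estimated correlation the adjusted p = 0.261, and fry gave an adjusted p = 0.00356. The matrilysin gene MMP7 was at -0.26 ± 0.07, SNAI2, a repressor of epithelial genes, at -0.34 ± 0.09, and the protease inhibitor gene TIMP2 at 0.13 ± 0.04, none past the threshold over all genes. Genes of NF-kB targets had a median of -0.04, with IL6 past the threshold and the adhesion receptor gene ICAM1 at -0.16 ± 0.04 (adjusted p = 0.0518). Of these 41 genes 1 fell over all genes, and 6 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.00521, adjusted p = 0.442 with an estimated correlation). Cholesterol synthesis genes, among them FDPS at 0.18 ± 0.05, had a median of 0.08, with 0 of 25 past over all genes and 7 that rose adjusted over the list alone (camera adjusted p = 0.000515, adjusted p = 0.648 with an estimated correlation). Mitosis genes, such as TOP2A at 0.18 ± 0.05, had a median of 0.06, with 0 of 40 past over all genes and 7 that rose adjusted over the list alone (camera adjusted p = 0.000462, adjusted p = 0.790 with an estimated correlation). Interferon response genes had a median of -0.03 with OAS3 at -0.27 ± 0.07, 0 of 42 past over all genes and 2 that fell adjusted over the list alone (camera adjusted p = 0.0188, adjusted p = 0.739 with an estimated correlation). Genes of p53 targets and apoptosis had a median of 0.05, with 0 of 28 past over all genes, and 8 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.0346, adjusted p = 0.607 with an estimated correlation). Chemokines and cytokines had a median of -0.02, with IL6 past the threshold among 36 genes and CCL2 at -0.28 ± 0.09, and 2 fell adjusted over the list alone (camera adjusted p = 0.0338, adjusted p = 0.385 with an estimated correlation). The RNA measure was 0.235 higher in the TW212 tumours than in the vehicle tumours of this comparison, and the mean of skin epithelium markers differed by -0.05 (n = 20 each, permutation p = 0.0145, adjusted p = 0.0497).

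A further question was when the TW212 response appeared. At 4 h the interferon response genes OAS3 (-0.55 ± 0.14), IFI44L (-0.55 ± 0.15) and IFIT1 (-0.44 ± 0.13) lay below the vehicle mean in all 5 treated tumours without passing the threshold over all genes. IFI44L was at 6.44 in the vehicle tumours of 4 h, at 5.89 with TW212 at 4 h, and from 5.82 to 6.28 in the vehicle tumours of the other times. The list had a median of -0.11 with 0 of 42 genes past over all genes and 6 that fell adjusted over the list alone (camera adjusted p = 1.52e-06, adjusted p = 0.370 with an estimated correlation). Heat shock response genes, which code for protein-folding chaperones, had a median of -0.14 at 4 h, with HSPH1 at -0.30 ± 0.09 and DNAJA1 at -0.24 ± 0.07. HSPH1 was at 10.42 in the vehicle tumours of 4 h, at 10.11 with TW212 and 10.08 with B20.4.1 at 4 h, and from 10.09 to 10.23 in the vehicle tumours of the other times. None of the 18 heat shock genes passed over all genes and 7 fell adjusted over the list alone (camera adjusted p = 6.85e-06, adjusted p = 0.370 with an estimated correlation). Fibroblast and pericyte markers had a median of -0.06, with the protease gene FAP at -0.34 ± 0.11 and the matrix proteoglycan gene DCN at -0.38 ± 0.14, 0 of 20 past over all genes and 1 that fell adjusted over the list alone (camera adjusted p = 0.00262, adjusted p = 0.370 with an estimated correlation). Circadian clock genes had a median of 0.07 with PER2 at 0.30 ± 0.11, 0 of 20 past over all genes and 0 adjusted over the list alone (camera adjusted p = 0.0462, adjusted p = 0.607 with an estimated correlation). No single gene passed at 4 h with limma, where 1673 of 19775 had an unadjusted p below 0.05.

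Hypoxia response genes lay above the vehicle tumours with TW212 at 8 h and below them at 24 h, and no gene passed the test of a TW212 effect that differs between times. The vehicle tumours themselves moved, with VEGFA at 10.70 at 8 h and 11.11 at 24 h, beside 10.90 and 10.84 with TW212. At 8 h the median of the hypoxia list was 0.21, with 37 of 43 higher, ANGPTL4, a lipase inhibitor, at 0.57 ± 0.17 and the hormone gene STC2 at 0.44 ± 0.13. None passed over all genes and 14 rose adjusted over the list alone (camera adjusted p = 5.71e-14, adjusted p = 0.370 with an estimated correlation). At 24 h the median was -0.21, with 38 of 43 lower, the glucose transporter gene SLC2A3 at -0.52 ± 0.15 and ANKRD37 at -0.66 ± 0.18, and 0 past over all genes while 17 fell adjusted over the list alone (camera adjusted p = 3.50e-15, adjusted p = 0.370 with an estimated correlation). Unfolded protein and integrated stress response genes had a median of 0.12 at 8 h, with the transcription factor genes CEBPB at 0.33 ± 0.09 and DDIT3 at 0.36 ± 0.12. Of these 32 genes 0 passed over all genes and 10 rose adjusted over the list alone (camera adjusted p = 4.83e-08, adjusted p = 0.370 with an estimated correlation). Glucocorticoid response genes had a median of 0.08 at 8 h, 0 of 17 past over all genes and 1 that rose adjusted over the list alone (camera adjusted p = 0.0176, adjusted p = 0.442 with an estimated correlation). The RNA measure was 0.98 ± 0.33 with TW212 and 0.73 ± 0.16 with vehicle at 8 h (SD, n = 5 each, exact permutation p = 0.151, adjusted p = 0.415).

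Cholesterol synthesis and cell division genes were higher with TW212 than in the vehicle tumours of 24 h. HMGCS1, an early enzyme of the pathway, was at 0.44 ± 0.13 and NSDHL at 0.39 ± 0.12, and the list had a median of 0.22 with 24 of 25 higher. None passed over all genes and 8 rose adjusted over the list alone (camera adjusted p = 2.28e-10, adjusted p = 0.370 with an estimated correlation). The mitotic kinase gene AURKA was at 0.29 ± 0.09 and the kinetochore gene NDC80 at 0.34 ± 0.11, in a list of 40 with a median of 0.16, of which 0 passed over all genes and 8 rose adjusted over the list alone (camera adjusted p = 6.95e-09, adjusted p = 0.607 with an estimated correlation). Genes of DNA replication and G1/S, such as RRM1 at 0.22 ± 0.07, had a median of 0.10 with 0 of 39 past over all genes and 0 adjusted over the list alone (camera adjusted p = 0.00275, adjusted p = 0.774 with an estimated correlation). NF-kB targets had a median of -0.10, with ICAM1 at -0.25 ± 0.08 and the prostaglandin synthase gene PTGS2 at -0.52 ± 0.17 but NFKBIZ, an NF-kB cofactor, at 0.45 ± 0.15. None of the 41 passed over all genes, and 4 fell and 2 rose adjusted over the list alone (camera adjusted p = 0.000809, adjusted p = 0.370 with an estimated correlation). The RNA measure was 0.367 higher in the TW212 than in the vehicle tumours of 24 h (n = 5 each, exact permutation p = 0.127, adjusted p = 0.415). With limma no gene passed at 8 h, where 1346 had an unadjusted p below 0.05, or at 24 h, where 2282 did. Between TW212 and B20.4.1 at 24 h 0 genes passed, and 845 had an unadjusted p below 0.05. The mitosis list had the same median of 0.16 with B20.4.1 at 24 h, against the same vehicle tumours. A TW212 effect on the lists of 24 h cannot be told apart from vehicle tumours of 24 h that are out of place.

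At 72 h, TW212 raised KANSL1L by 0.65 ± 0.12 (SE, n = 5 per group, adjusted p = 0.0173) and SOCS3, a feedback inhibitor of cytokine receptors, by 0.58 ± 0.12 (adjusted p = 0.0492). RELT, a receptor of the TNF receptor family, fell by 0.36 ± 0.07 (adjusted p = 0.0492). The fourth gene to pass was a gene of the Y chromosome, whose levels are not given here. NF-kB target genes had a median of -0.07 with TNF at -0.26 ± 0.08 and TRAF1 at -0.29 ± 0.10, 0 of 41 past over all genes and 2 that fell adjusted over the list alone (camera adjusted p = 0.00212, adjusted p = 0.395 with an estimated correlation). In the vehicle tumours this list had a median of 0.15 from 4 h to 72 h, so a fall with TW212 cannot be told apart from that rise. All 4 genes had the same sign in both array sets, and another probe set of KANSL1L and of SOCS3 pointed the other way. Without TW212 72 h tumour 2 or 5, or without vehicle 72 h tumour 1, none passed. Against the vehicle tumours of the other 3 times the changes were a median of 0.237 of their size, and none of the 4 passed. The 4 genes also passed between 72 h and 4 h in the vehicle tumours with the opposite sign, which the vehicle tumours of 72 h that both comparisons share favour by design.

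**Figure D3:**
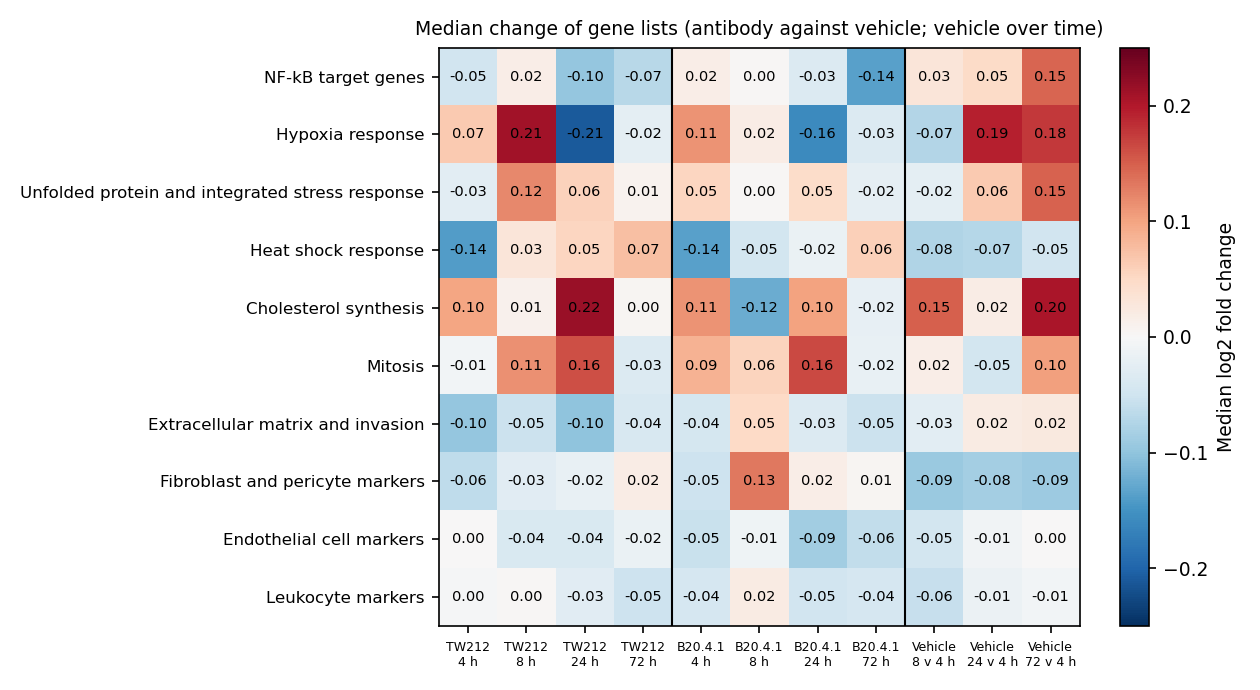
Median log2 fold change (colour and printed value) of 10 gene lists (vertical axis), for each antibody against vehicle at each time and for vehicle tumours against 4 h (horizontal axis). The hypoxia response list stands at 0.21 with TW212 at 8 h and at -0.21 at 24 h.

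The B20.4.1 comparisons asked what blocking VEGF changed in the tumours. At 4 h CRIP2, a LIM domain protein gene, rose by 0.40 ± 0.07 (SE, n = 5 per group, adjusted p = 0.00478), the long noncoding RNA LINC02274 by 0.48 ± 0.10 and the transcription factor gene GLIS2 by 0.35 ± 0.07. PPP3CA, the catalytic subunit of the phosphatase calcineurin, fell by 0.45 ± 0.08 (adjusted p = 0.00478). Heat shock response genes had a median of -0.14 against the same vehicle tumours as with TW212, with HSPH1 at -0.34 ± 0.09 and HSP90AA1 at -0.20 ± 0.05. None of the 18 passed over all genes, and 6 fell and 2 rose adjusted over the list alone (camera adjusted p = 0.000148, adjusted p = 0.370 with an estimated correlation). Oxidative phosphorylation genes had a median of 0.09, with CYC1 at 0.24 ± 0.07, 0 of 29 past over all genes and 2 that rose adjusted over the list alone (camera adjusted p = 3.39e-05, adjusted p = 0.607 with an estimated correlation). The 4 genes past the threshold at 4 h each had the same sign in both array sets. All 4 also passed between 72 h and 4 h in vehicle tumours with the same sign, and both comparisons use the vehicle tumours of 4 h, in which GLIS2 (9.71) and PPP3CA (10.61) had their lowest and highest mean of the 12 groups. Another probe set of PPP3CA pointed the other way, and without vehicle 4 h tumour 2 only 1 gene passed. Against the vehicle tumours of the other 3 times the median was 0.397 of the change, and none of the 4 passed.

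With limma no gene passed at 8 h with B20.4.1, and 582 of 19775 had an unadjusted p below 0.05. The smallest p belonged to HSD17B7P2 (-0.34 ± 0.09), LINC01270 (-0.28 ± 0.07) and the cortisol-activating enzyme gene HSD11B1 (-0.35 ± 0.10), none past the threshold. Cholesterol synthesis genes had a median of -0.12 with NSDHL at -0.24 ± 0.12 and 0 of 25 past over all genes or adjusted over the list alone (camera adjusted p = 2.10e-06, adjusted p = 0.555 with an estimated correlation). Fibroblast and pericyte markers had a median of 0.13, with MFAP5 at 0.26 ± 0.10, and 0 of 20 past over all genes or adjusted over the list alone (camera adjusted p = 0.000180, adjusted p = 0.370 with an estimated correlation).

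At 24 h B20.4.1 lowered ANKRD37, a gene switched on by low oxygen, by more than any other gene that passed. ANKRD37 fell by 0.81 ± 0.18, or 1.75-fold (SE, n = 5 per group, adjusted p = 0.0427), IGFBP5, a binding protein of insulin-like growth factors, fell by 0.39 ± 0.08, and PRAMEF10 fell by 0.50 ± 0.10. SS18L1, a subunit of a chromatin remodelling complex, rose by 0.61 ± 0.12, the Wnt ligand gene WNT2B by 0.58 ± 0.11, and PRICKLE1, a gene of planar cell polarity, by 0.54 ± 0.10 (each adjusted p = 0.0187). GXYLT1, a sugar transferase of Notch proteins, rose by 0.48 ± 0.10, the mitochondrial coactivator gene PPRC1 by 0.40 ± 0.09, and PLAU, the protease urokinase, by 0.30 ± 0.06. The other named rises were ZNF451 (0.42 ± 0.09), C8orf33 (0.36 ± 0.08), FAM217B (0.35 ± 0.08) and ZNF655 (0.32 ± 0.07). In all 14 genes passed, 11 higher and 3 lower, all with the same sign in both array sets.

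Hypoxia response genes had a median of -0.16 with B20.4.1 at 24 h, with ANKRD37 past the threshold, the lipid droplet gene HILPDA at -0.51 ± 0.15 and DDIT4 at -0.40 ± 0.12. Over all genes 1 of 43 fell and adjusted over the list alone 3 fell (camera adjusted p = 5.56e-06, adjusted p = 0.607 with an estimated correlation). Mitosis genes had a median of 0.16, with the proliferation marker MKI67 at 0.37 ± 0.10 and CENPF at 0.42 ± 0.11, 0 of 40 past over all genes and 14 that rose adjusted over the list alone (camera adjusted p = 6.95e-09, adjusted p = 0.607 with an estimated correlation). Immediate early and MAPK feedback genes had a median of -0.11, with SPRY1, an inhibitor of growth factor signals, at -0.42 ± 0.12, and 0 of 34 past over all genes and 1 that fell adjusted over the list alone (camera adjusted p = 0.000462, adjusted p = 0.370 with an estimated correlation). The RNA measure was 0.367 higher in the B20.4.1 than in the vehicle tumours of 24 h. With that measure in the model the changes were a median of 0.825 of their size, all 14 with the same sign, and none passed. Without vehicle 24 h tumour 2 or 5, or B20.4.1 24 h tumour 3 or 4, the count was also 0. Other probe sets of ANKRD37 and ZNF451 pointed the other way.

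At 72 h B20.4.1 changed genes in both directions, among them the urokinase receptor and a chaperone partner. PLAUR, which codes for that receptor, fell by 0.38 ± 0.09 (SE, n = 5 per group, adjusted p = 0.0483), LCN2, a secreted iron-binding protein, by 0.58 ± 0.13, and RELT by 0.39 ± 0.07 (adjusted p = 0.0138). DEFB126, a defensin gene, fell by 0.39 ± 0.08, the sodium-coupled transporter gene SLC5A11 by 0.40 ± 0.09, the antisense RNA RALY-AS1 by 0.47 ± 0.08, and the receptor gene GPR176 by 0.29 ± 0.07. KANSL1L rose by 0.69 ± 0.12 (adjusted p = 0.00475), SOCS3 by 0.54 ± 0.12, the integrin gene ITGB8 by 0.54 ± 0.13, and the ciliary transcription factor gene RFX3 by 0.54 ± 0.12. EPHA7, a receptor of ephrins, rose by 0.47 ± 0.10 and CHORDC1, a partner of the chaperone HSP90, by 0.46 ± 0.10. The mitochondrial gene ND6 (0.56 ± 0.13), DPY19L2 (0.60 ± 0.13), ZMYM5 (0.49 ± 0.11) and PAXIP1-AS2 (0.45 ± 0.10) were the other named rises. In all 30 genes passed, 23 higher and 7 lower, and all had the same sign in both array sets. KANSL1L, SOCS3 and RELT had also passed with TW212 at 72 h, against the same vehicle tumours. Each also passed between 72 h and 4 h in vehicle tumours with the opposite sign. Simulated unchanged groups set against the same vehicle tumours shared 0 genes in each of 100 draws. Groups without changed genes give few calls past the threshold, so that 0 cannot weigh the sharing. Independent lists would share 0.00607, a value that leaves out the shared vehicle tumours. At an unadjusted p below 0.05 the comparisons shared 680 genes with the same sign, within the 0 to 1791 of the simulated groups. DEFB126, SLC5A11 and RALY-AS1 lay under the median of all probe sets.

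NF-kB target genes had a median of -0.14 with B20.4.1 at 72 h, with NFKBIE at -0.24 ± 0.06 and ICAM1 at -0.28 ± 0.08. None of the 41 passed over all genes and 4 fell adjusted over the list alone (camera adjusted p = 0.00128, adjusted p = 0.370 with an estimated correlation). From 4 h to 72 h this list had a median of 0.15 in the vehicle tumours and 0.04 in the average of the antibody arms. A fall with B20.4.1 cannot be told apart from a rise in the vehicle tumours of 72 h, which both comparisons share. Genes of p53 targets and apoptosis had a median of 0.06, with TP53INP1 past the threshold at 0.38 ± 0.08 and the p53 inhibitor gene MDM2 at 0.26 ± 0.08. Of these 28 genes 1 rose over all genes and 3 rose adjusted over the list alone (camera adjusted p = 0.00121, adjusted p = 0.370 with an estimated correlation). Skeletal muscle markers had a median of -0.15, with TNNC2 at -0.37 ± 0.12, 0 of 22 past over all genes and 3 that fell adjusted over the list alone (camera adjusted p = 0.00142, adjusted p = 0.370 with an estimated correlation). Skin epithelium markers had a median of -0.09, with the keratin gene KRT14 at -0.83 ± 0.28 and 0 of 14 past over all genes or adjusted over the list alone (camera adjusted p = 0.0462, adjusted p = 0.370 with an estimated correlation). Of the 30 genes, 10 also passed between 72 h and 4 h in vehicle tumours with the opposite sign, which the shared vehicle tumours of 72 h favour by design. Against the vehicle tumours of the other 3 times the median was 0.402 of the change, and 3 of the 30 passed. Without B20.4.1 72 h tumour 2 or vehicle 72 h tumour 1 none passed, and other probe sets of RFX3, ITGB8, SOCS3 and PAXIP1-AS2 pointed the other way.

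Averaged over the 4 times, EDRF1 alone passed with B20.4.1, rising by 0.18 ± 0.03 (SE, n = 20 per arm, adjusted p = 0.0480), although another of its probe sets pointed the other way and the call was lost without the array set term. Several marker lists were read on human probe sets, although the host tissue is of the mouse. The mean of endothelial markers was 5.16 with B20.4.1 and 5.21 with vehicle, and that of skin markers 4.93 and 4.99, all under the median of 5.37 over all probe sets. Endothelial cell markers had a median of -0.04, with PLVAP, a protein of vessel wall pores, at -0.16 ± 0.05 and SOX18 at -0.18 ± 0.06. None of the 22 passed over all genes and 2 fell adjusted over the list alone (camera adjusted p = 0.0153, adjusted p = 0.535 with an estimated correlation). Their mean level differed from vehicle by -0.05 (n = 20 each, permutation p = 0.00359, adjusted p = 0.0307). Erythroid markers had a median of -0.07 with HBB at -0.15 ± 0.08, and 0 of 6 passed over all genes or adjusted over the list alone (camera adjusted p = 0.0246, adjusted p = 0.427 with an estimated correlation). Leukocyte markers had a median of -0.05 with AIF1 at -0.31 ± 0.11, and 0 of 22 passed over all genes or adjusted over the list alone (camera adjusted p = 0.0440, adjusted p = 0.708 with an estimated correlation). The mean level differed from vehicle by -0.06 for skin epithelium markers (n = 20 each, permutation p = 0.00384, adjusted p = 0.0307), by -0.08 for erythroid markers (permutation p = 0.00882, adjusted p = 0.0423) and by -0.05 for leukocyte markers (permutation p = 0.0550, adjusted p = 0.147). Fibroblast and pericyte markers differed by 0.04 (permutation p = 0.118, adjusted p = 0.263). All 40 mitosis genes were higher, with a median of 0.07 and KIF11 at 0.12 ± 0.04, and 0 passed over all genes or adjusted over the list alone (camera adjusted p = 4.23e-08, adjusted p = 0.609 with an estimated correlation).

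The last lists of the averaged comparisons did not pass camera with either antibody. VEGF family and angiogenic factors had a median of -0.03 with B20.4.1 (camera adjusted p = 0.511), with 0 of 31 past over all genes or adjusted over the list alone. Kidney tubule identity genes had a median of -0.04 with B20.4.1 (camera adjusted p = 0.455), with 0 of 23 past over all genes or adjusted over the list alone. Ribosomal protein genes were at -0.01 with TW212 (camera adjusted p = 0.993), with 0 of 21 past over all genes or adjusted over the list alone. Adipocyte markers were at -0.04 with B20.4.1 (camera adjusted p = 0.265), with 0 of 13 past over all genes or adjusted over the list alone, and their mean level differed from vehicle by -0.04 (n = 20 each, permutation p = 0.00188, adjusted p = 0.0307).

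The direct comparison of the antibodies asked what set TWEAK blockade apart from VEGF blockade. At 8 h TRIB3, a pseudokinase of the integrated stress response, was higher with TW212 by 0.50 ± 0.09 (SE, n = 5 per group, adjusted p = 0.0296), and it was the only gene past the threshold at that time. DDIT3, another gene of that response, was at 0.41 ± 0.12, and the list had a median of 0.11 with 1 of 32 higher over all genes, and 11 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.53e-05, adjusted p = 0.413 with an estimated correlation). Hypoxia response genes had a median of 0.20, with NDRG1 at 0.45 ± 0.14 and DDIT4 at 0.44 ± 0.12, 0 of 43 past over all genes, and 18 higher and 1 lower adjusted over the list alone (camera adjusted p = 3.27e-10, adjusted p = 0.442 with an estimated correlation). Averaged over time, SERPINI1, which codes for neuroserpin, was lower with TW212, at -0.35 ± 0.06 (n = 20 per arm, adjusted p = 0.00420, level 4.67 against 5.02), as were the transcription factor gene NFE2L3 at -0.25 ± 0.05 and the protease gene PRSS23 at -0.24 ± 0.05. The long noncoding RNA RMST was higher by 0.19 ± 0.04 (level 4.96 against 4.77), and like SERPINI1 it lay under the median of 5.37 over all probe sets. Fibroblast and pericyte markers had a median of -0.08, with FAP at -0.17 ± 0.05 and THY1 at -0.14 ± 0.05, 0 of 20 past over all genes and 3 lower adjusted over the list alone (camera adjusted p = 0.000616, adjusted p = 0.370 with an estimated correlation). Their mean level differed by -0.07 (n = 20 each, permutation p = 0.00796, adjusted p = 0.0423). No gene passed with limma at 4, 24 or 72 h, where 2786, 845 and 964 had an unadjusted p below 0.05. The RNA measure at 8 h was 0.98 ± 0.33 with TW212 and 0.66 ± 0.22 with B20.4.1 (SD, n = 5 each). With that measure in the model neither TRIB3 nor any of the 4 genes of the average passed. TRIB3 was also lost without the tumours above 1 in that measure, with no array set term, and without TW212 8 h tumour 3 or 5 or B20.4.1 8 h tumour 3, 4 or 5.

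The vehicle tumours were also compared between times. Between 4 h and 72 h the adhesion gene FLRT3 fell by 1.08 ± 0.18, or 2.12-fold (SE, n = 5 per time, adjusted p = 0.000443). ALOX5, the enzyme that starts leukotriene synthesis, fell by 0.67 ± 0.12, CAVIN2, a caveolae protein gene, by 0.67 ± 0.12, and EPHA7 by 0.64 ± 0.10 (adjusted p = 7.97e-05). KRT7, a keratin of simple epithelia, rose by 0.68 ± 0.10 (adjusted p = 6.15e-05), the chemokine gene CCL2 by 0.77 ± 0.17, ANGPTL4 by 0.76 ± 0.17, and DUSP5, a phosphatase that limits ERK, by 0.69 ± 0.13. SLCO4A1 (0.92 ± 0.22), the troponin gene TNNC1 (0.77 ± 0.19), FAM110C (0.69 ± 0.14), UPP1 (0.68 ± 0.16), TAGLN (0.63 ± 0.17) and LAT (0.61 ± 0.10) were the other named rises. The other named falls were ENPP5 (-0.63 ± 0.16), IFI44L (-0.62 ± 0.15), NID2 (-0.62 ± 0.14), CDKN2AIP (-0.61 ± 0.15), PLA2G4A (-0.54 ± 0.14) and SPATA13 (-0.53 ± 0.13). ENPP5 and PLA2G4A lay under the median of all probe sets. In all 256 genes passed, 192 higher and 64 lower, all with the same sign in both array sets. No gene passed at 8 h or 24 h with limma, where 1130 and 979 had an unadjusted p below 0.05.

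Several lists moved with the vehicle tumours between 4 h and 72 h. NF-kB target genes had a median of 0.15, and TNF (0.36 ± 0.08), NFKBIE (0.33 ± 0.06), TNIP1 (0.34 ± 0.08) and CCL2 rose. Of the 41 genes 6 rose over all genes and 12 rose adjusted over the list alone (camera adjusted p = 1.98e-06, fry adjusted p = 0.00221), with an adjusted p = 0.199 with an estimated correlation. All 12 measured genes of the TWEAK receptor pathway were higher, with a median of 0.16, and 1, the NF-kB inhibitor gene TNFAIP3, rose over all genes (0.39 ± 0.09) and 3 rose adjusted over the list alone (camera adjusted p = 0.000156, fry adjusted p = 0.00815). With an estimated correlation the adjusted p = 0.203. This list shares TRAF1, BIRC3, NFKB2, RELB and TNFAIP3 with the NF-kB target list, so these lists are not independent. Unfolded protein and integrated stress response genes had a median of 0.15, and the amino acid transporter gene SLC3A2 (0.55 ± 0.08), TRIB3 (0.48 ± 0.09) and ASNS (0.48 ± 0.10) rose. Of 32 genes 6 rose over all genes, and 13 rose and 2 fell adjusted over the list alone (camera adjusted p = 2.80e-08, fry adjusted p = 0.00815), with an adjusted p = 0.203 with an estimated correlation. Hypoxia response genes had a median of 0.18, with HK1 (0.28 ± 0.06) and HK2 (0.51 ± 0.14) among 4 of 43 that rose over all genes and 14 that rose adjusted over the list alone (camera adjusted p = 2.96e-11, adjusted p = 0.311 with an estimated correlation). Cholesterol synthesis genes had a median of 0.20, with SCD (0.50 ± 0.12) and MVD (0.41 ± 0.10) among 3 of 25 that rose over all genes and 8 that rose adjusted over the list alone (camera adjusted p = 2.80e-08, adjusted p = 0.321 with an estimated correlation). Interferon response genes had a median of -0.10, with IFI44L, HERC5 (-0.37 ± 0.09) and IFI6 (-0.50 ± 0.13) past the threshold. Of these 42 genes 3 fell over all genes, and 8 fell and 1 rose adjusted over the list alone (camera adjusted p = 1.97e-06, adjusted p = 0.311 with an estimated correlation). The RNA measure was 0.63 ± 0.22 at 72 h and 0.67 ± 0.36 at 4 h (SD, n = 5 each, exact permutation p = 0.810). Another probe set of ALOX5 pointed the other way. The count was 82 without vehicle 4 h tumour 2, 98 and 105 without vehicle 72 h tumours 1 and 4, and 35 when the change was taken from the antibody arms instead, of which 4 were among the 256.

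**Figure D4:**
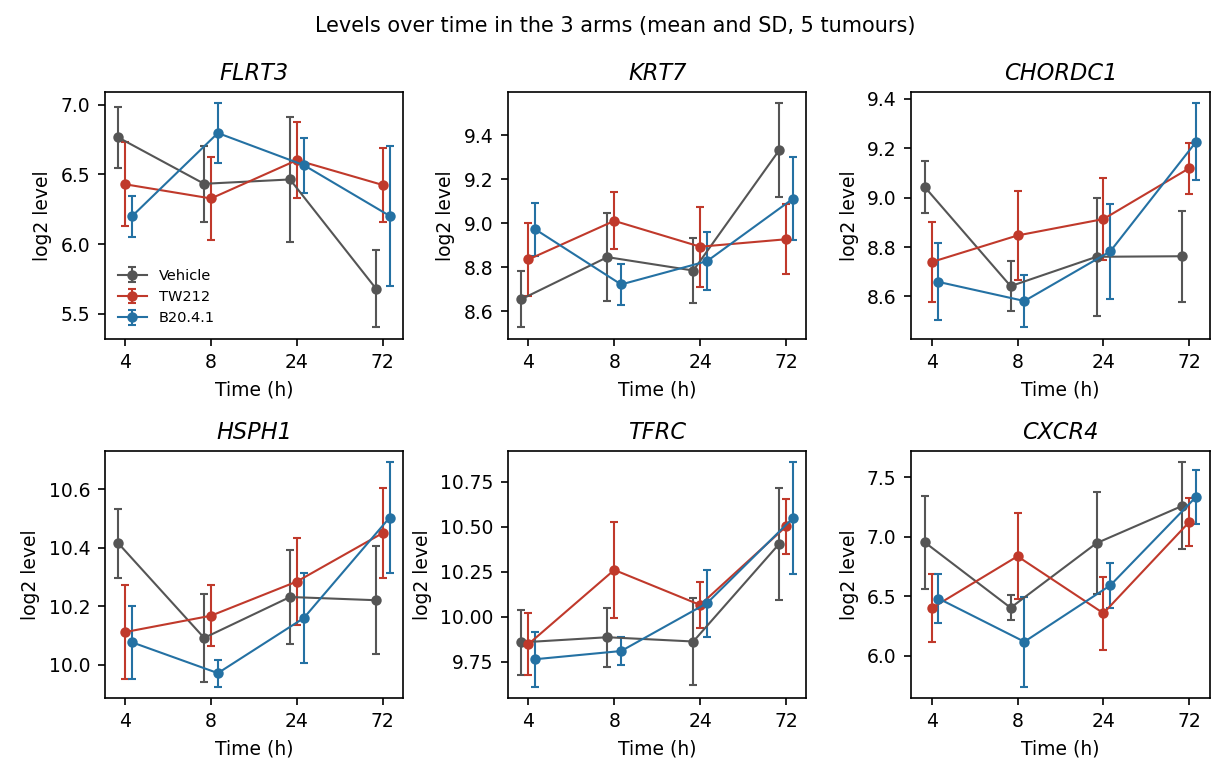
Levels (log2, vertical axis) of 6 genes at each time in hours (horizontal axis) for the 3 arms, as the mean and SD of 5 tumours, with lines joining groups of different tumours. FLRT3 fell by 1.08 from 4 h to 72 h with vehicle, while TFRC rose by 0.66 in the average of the 3 arms.

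The design also asks whether an antibody's effect changed with time. CHORDC1 alone passed for B20.4.1, with a difference from vehicle of -0.38 at 4 h, -0.06 at 8 h, 0.02 at 24 h and 0.46 at 72 h (SE 0.10 each, n = 5 per group, adjusted p = 0.0268). Its vehicle level was 9.04 at 4 h and 8.64, 8.76 and 8.76 at the later times. With B20.4.1 it was at 8.66, 8.58, 8.78 and 9.23, so the -0.38 goes with a vehicle group above those of the other times. As many genes came from 5 of 100 splits of the same tumours. Of 40 tumours left out singly, 8 took the count to 0. The same gene with TW212 was at -0.30, 0.21, 0.15 and 0.36 and did not pass (adjusted p = 0.443). No gene passed for TW212 with limma, where 1049 of 19775 had an unadjusted p below 0.05.

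Across genes, the TW212 and B20.4.1 changes averaged over time had a correlation of 0.534, for which genes are not independent replicates. Both changes use the same vehicle tumours, and simulated unchanged groups set against those tumours gave a mean correlation of 0.482 (range -0.07 to 0.815 over 100 draws). With the vehicle tumours divided between the comparisons the mean was 0.248, from -0.17 to 0.498. At an unadjusted p below 0.05 the antibodies shared 696 genes that were higher and 332 that were lower, where simulated unchanged groups shared 0 to 560 and 0 to 495 (means 87.8 and 82.0) and independent lists would share 165 and 108. In opposite directions 1 gene was shared, with 0 to 4 in the simulated groups and 279 for independent lists. MMP13, IGF1 and SS18L1 were at -0.24 ± 0.05, -0.23 ± 0.08 and 0.24 ± 0.06 with B20.4.1, without passing, and were chosen here after their values were seen.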

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

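Chance splits, the share of the vehicle time effect found in the antibody arms and the comparison of 24 h vehicle tumours with other vehicle tumours had predictions written before the results of those tests were seen, but not before any values had been seen. The tests that add the RNA measure or the leukocyte marker mean to the model, and the direct test of vehicle against antibody arms, were chosen only after the result was seen.

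Several tumours lay far from the others of their group. The RNA measure of vehicle 4 h tumour 3 was 1.29, beside 0.445 to 0.677 in the other tumours of that group. The same tumour had PLA2G4A at 3.15, beside 3.87 to 4.05. In vehicle 72 h tumour 1, VEGFA was at 10.99 (others 11.14 to 11.19), LCN2 at 6.74 (6.23 to 6.32) and NID2 at 5.79 (6.36 to 6.58). In the 24 h groups, WNT2B was at 6.30 in vehicle tumour 5 (6.69 to 6.81), PPRC1 at 8.41 in vehicle tumour 4 (8.2 to 8.26) and GXYLT1 at 8.66 in B20.4.1 tumour 3 (8.39 to 8.47). In all 8 of 160 groups held such a tumour, and chance sets apart a tumour in about 1 of 20 groups, or 8 here.

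Some effects differed between groups by a test of the difference itself. The B20.4.1 effect on CHORDC1 was 0.46 at 72 h and -0.38 at 4 h (adjusted p = 0.0268 over all genes for a difference between times). The vehicle level of CHORDC1 was 9.04 at 4 h and from 8.64 to 8.76 at the later times. For 18 genes the change from 4 h to 72 h differed between the vehicle tumours and the average of the antibody arms. CHORDC1 stood at -0.75 ± 0.12 for vehicle minus antibody arms, HSPH1 at -0.58 ± 0.11, FLRT3 at -1.08 ± 0.22 and KRT7 at 0.56 ± 0.12 (SE, limma). Among 13522 probe sets that do not name exactly 1 gene, which the comparisons leave out, 1 passed for TW212 at 4 h, 2 for TW212 averaged over time and 16 for vehicle tumours at 72 h against 4 h.

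For several counts, other splits of the same tumours seldom gave as many genes. With 100 splits the smallest possible share is 1 in 100. No correction was made over the comparisons, so chance is not excluded for any single count. The real value and the highest of the other splits were 43 and 3 for TW212 averaged over time, 256 and 22 for vehicle tumours at 72 h, 30 and 14 for B20.4.1 at 72 h, and 14 and 1 for B20.4.1 at 24 h. They were 4 and 1 for B20.4.1 at 4 h and 4 and 3 for TW212 at 72 h, and in each of these comparisons only 1 of 100 splits, the real split, gave as many genes. For TW212 against B20.4.1 averaged over time 2 of 100 gave as many, with 4 in the real split and 1020 in another. As many genes came up more often for B20.4.1 averaged over time (8 of 100 splits, 1 and 4) and TW212 against B20.4.1 at 8 h (12 of 100, 1 and 2). The same held for the B20.4.1 effect across times (5 of 100, 1 and 3), and chance stays open for all of these. Where the real count was 0, all 100 splits gave as many, and the highest other count was 9 for TW212 at 4 h, 1 at 8 h and 11 at 24 h, 1 for B20.4.1 at 8 h, 5, 2 and 1 for TW212 against B20.4.1 at 4, 24 and 72 h, 2 and 4 for vehicle tumours at 8 and 24 h, and 666 for the TW212 effect across times. Why the splits with 1020 and 666 gave so many genes was not tested.

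The first pattern weighed was the 43 genes of TW212 averaged over time. With the RNA measure in the model their fold changes were a median of 0.699 of the original (quartiles 0.579 to 0.816), the median size went from 0.21 to 0.14 with SE from 0.0469 to 0.0413, the median t went from 4.48 to 3.46, and 2 stayed past the threshold, with 5 under the largest p that had passed before. A TW212 effect and a difference in RNA integrity between the arms cannot be told apart from these values. With the leukocyte marker mean in the model the median was 0.888 and 25 stayed past the threshold, but host leukocyte content stays open, since these human probe sets lay at a mean of 5.16 with TW212 and 5.2 with vehicle, under the median of 5.37 over all probe sets. What stays open too is how far RNA integrity, which differed between the arms, was itself a result of treatment.

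The second pattern was the 256 genes of the vehicle tumours at 72 h. The median ratio was 1.01 with the RNA measure in the model, with 256 still past the threshold. The measure was 0.63 at 72 h and 0.67 at 4 h, so this term could move the changes little. That small difference, rather than the ratio, argues against RNA integrity as the whole cause. With the leukocyte marker mean the median ratio was 0.991, and the low level of these markers leaves host leukocyte content open. For 52 genes chosen in array set 1, the antibody arms moved by 0.12 (permutation p = 0.00037) and the 2 vehicle tumours of 72 h in array set 2 by 0.34 from the 2 of 4 h, a share of 0.362. A direct test over all genes argues against a time effect of the same size in every arm for 13 of the 256 genes, among them FLRT3. For the rest, an effect of the same size and a larger effect in vehicle tumours cannot be told apart with so few vehicle tumours in array set 2, and no biological explanation was tested.

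The third pattern was the 14 genes of B20.4.1 at 24 h. With the RNA measure in the model the median ratio was 0.825 (quartiles 0.746 to 0.875), the median size went from 0.41 to 0.33 with SE from 0.0895 to 0.0765, the median t went from 4.91 to 4.24, and none stayed past the threshold, with 3 under the largest p that had passed before. Against the vehicle tumours of the other 3 times the median ratio was 0.618 (quartiles 0.490 to 0.654), all 14 kept their sign and 1 was still past the threshold. The same ratio was 0.237 for TW212 at 72 h (0 of 4 genes still past), 0.397 for B20.4.1 at 4 h (0 of 4) and 0.402 for B20.4.1 at 72 h (3 of 30, 28 with the same sign), all under the 0.5 set in advance for vehicle tumours of 24 h out of place. A B20.4.1 effect cannot be told apart from a difference in RNA integrity or from vehicle tumours of 24 h that are out of place.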

How the results depend on the processing

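The terms for leukocyte markers, the removal of tumours above 1 in the RNA measure, the average of the antibody arms, and the RNA term on the time, antibody against antibody, interaction and list results were added after the data were seen, and the other alternatives were fixed before the data were examined. No paired analysis was possible because the labels carry no number that ties a tumour of a group to a tumour of another group. Where a count is given below, the counts it replaces are 4 for TW212 at 72 h, 4, 14 and 30 for B20.4.1 at 4, 24 and 72 h, 43, 1 and 4 for the averages over time of TW212, B20.4.1 and TW212 against B20.4.1, 1 for TW212 against B20.4.1 at 8 h, 256 for vehicle at 72 h and 1 for the B20.4.1 effect across times, with 0 for the rest. All are limma counts, and those of 0 had 1673, 1346 and 2282 genes at an unadjusted p below 0.05 for TW212 at 4, 8 and 24 h and 582 for B20.4.1 at 8 h. The cause was not tested for any of the changes below, except that an array set alone, the groups compared alone and a single tumour left out use fewer tumours. Counts that are not given stayed within 1.5 times. Of 19775 genes, 13113 lay above the median of all probe sets. The fold changes of the other genes rest on lower signal, whose effect on them was not tested.

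With no array set term the counts were 8 for B20.4.1 at 24 h, 3 for B20.4.1 at 72 h, 0 for TW212 against B20.4.1 at 8 h and B20.4.1 averaged, and 2 for TW212 against B20.4.1 averaged. In array set 1 alone they were 0 for TW212 at 72 h, B20.4.1 at 24 h and 72 h, TW212 against B20.4.1 at 8 h, all 3 averages and the B20.4.1 effect across times, 2 for B20.4.1 at 4 h, 1 for vehicle at 24 h and 52 for vehicle at 72 h. In array set 2 alone they were 0 for TW212 at 72 h, B20.4.1 at 4, 24 and 72 h, TW212 against B20.4.1 at 8 h, TW212 averaged, B20.4.1 averaged, vehicle at 72 h and the B20.4.1 effect across times, and 1 for TW212 against B20.4.1 averaged.

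With the first arrays only, the counts were 1 for TW212 at 72 h, 27 for B20.4.1 at 24 h, 7 for B20.4.1 at 72 h and 175 for TW212 averaged. With the repeat arrays in place of the first arrays they were 6 for B20.4.1 at 24 h, 18 at 72 h and 0 averaged. With the repeat arrays as separate samples of a further array set they were 2 for TW212 at 72 h and B20.4.1 averaged, 411 for B20.4.1 at 24 h, 16 for B20.4.1 at 72 h and 167 for TW212 averaged.

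Quantile normalization between arrays again gave 2 for TW212 at 4 h, B20.4.1 at 4 h and TW212 against B20.4.1 at 8 h, 112 for TW212 averaged, 0 for B20.4.1 averaged, 1 for vehicle at 8 h and 5 for the B20.4.1 effect across times. Each array centred on its median gave 2 for TW212 at 72 h and B20.4.1 at 4 h, 16 for B20.4.1 at 72 h, 0 for TW212 against B20.4.1 at 8 h, 20 for TW212 averaged, 3 for B20.4.1 averaged, 1 for TW212 against B20.4.1 averaged and 142 for vehicle at 72 h.

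Only genes above the median of all probe sets gave 26 for B20.4.1 at 24 h, 295 for TW212 averaged, 3 for B20.4.1 averaged, 2 for TW212 against B20.4.1 averaged and 4 for the B20.4.1 effect across times. The probe set with the largest variance gave 0 for TW212 at 72 h, TW212 against B20.4.1 at 8 h and B20.4.1 averaged, 1 for B20.4.1 at 4 h, 2 for B20.4.1 at 72 h and 134 for vehicle at 72 h. With every probe set tested the counts were 2 for TW212 at 72 h and B20.4.1 at 4 h, 0 for B20.4.1 at 24 h, TW212 against B20.4.1 at 8 h and B20.4.1 averaged, 4 for B20.4.1 at 72 h, 1 for TW212 against B20.4.1 averaged and 3 for the B20.4.1 effect across times.

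The eBayes step with trend and robust gave 161 for TW212 averaged, 2 for B20.4.1 averaged and 7 for the B20.4.1 effect across times. Array weights gave 3 for TW212 at 4 h, 2 for TW212 at 72 h, 42, 277 and 144 for B20.4.1 at 4, 24 and 72 h, 16 for TW212 against B20.4.1 at 8 h, 1431, 262 and 80 for the averages of TW212, B20.4.1 and TW212 against B20.4.1, 1 for vehicle at 8 h and 65 for the B20.4.1 effect across times. With only the groups compared in the model the counts were 0 for TW212 at 72 h and TW212 against B20.4.1 at 8 h, 270 for B20.4.1 at 24 h, 2 for B20.4.1 at 72 h, B20.4.1 averaged and the B20.4.1 effect across times, 8 for TW212 averaged, 1 for TW212 against B20.4.1 averaged and 39 for vehicle at 72 h.

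The RNA quality term gave 23 for B20.4.1 at 4 h and the B20.4.1 effect across times, 0 for B20.4.1 at 24 h, TW212 against B20.4.1 at 8 h and TW212 against B20.4.1 averaged, 146 for B20.4.1 at 72 h, 4 for TW212 averaged, 32 for B20.4.1 averaged and 655 for vehicle at 72 h. The leukocyte marker term gave 1 for TW212 at 4 h and vehicle at 8 h, 2 for B20.4.1 at 4 h, 4 for B20.4.1 at 72 h, 0 for B20.4.1 averaged, 416 for vehicle at 72 h and 17 for the B20.4.1 effect across times. Without tumours above 1 in the RNA measure, which left 51 of 60, the counts were 1 for TW212 at 8 h and 72 h, 0 for B20.4.1 at 24 h and all 3 averages, 54 for B20.4.1 at 72 h and 4 for the B20.4.1 effect across times. With the antibody arms averaged in place of the vehicle tumours, 35 genes passed for 72 h against 4 h, and with all 3 arms averaged 236 did.

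Of 468 tests of gene lists 113 passed camera with the preset correlation, 0 with an estimated correlation and 4 with fry. The list tests of time changes averaged over arms or compared between arms, given below, are not among these. The correlation of the TW212 and B20.4.1 effects was 0.534 and was 0.248 with the vehicle tumours split between the comparisons.

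In leave-one-out, counts ran from 0 to 4 for TW212 at 72 h, 1 to 5 for B20.4.1 at 4 h, 0 to 114 at 24 h and 0 to 49 at 72 h. They ran from 0 to 7 for TW212 against B20.4.1 at 8 h, 0 to 1 at 24 h, 5 to 1298 for TW212 averaged, 0 to 14 for B20.4.1 averaged, 1 to 54 for TW212 against B20.4.1 averaged, 0 to 1 for vehicle at 8 h, 82 to 313 for vehicle at 72 h and 0 to 7 for the B20.4.1 effect across times, and stayed at 0 for the others. For TW212 at 72 h the count was 0 without TW212 tumour 2 or 5 or vehicle tumour 1, 1 without TW212 tumour 1 or 4 or vehicle tumour 4, and 2 without vehicle tumour 2, 3 or 5. For B20.4.1 at 4 h it was 1 without vehicle tumour 2 and 2 without B20.4.1 tumour 1 or 4 or vehicle tumour 1 or 4. For B20.4.1 at 24 h it was 0 without B20.4.1 tumour 3 or 4 or vehicle tumour 2 or 5, 2 and 5 without B20.4.1 tumours 2 and 5, and 114, 4 and 44 without vehicle tumours 1, 3 and 4. For B20.4.1 at 72 h it was 0 without B20.4.1 tumour 2 or vehicle tumour 1, 3, 10, 2 and 7 without B20.4.1 tumours 1, 3, 4 and 5, and 2, 49 and 11 without vehicle tumours 3, 4 and 5. For TW212 against B20.4.1 at 8 h it was 0 without TW212 tumour 3 or 5 or B20.4.1 tumour 3, 4 or 5, 2 without TW212 tumour 4 or B20.4.1 tumour 2, and 7 without TW212 tumour 2, and at 24 h it was 1 without B20.4.1 tumour 1.

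For TW212 averaged, leaving out 16 of 40 tumours lowered the count by over 1.5 times and 11 raised it. Left out among TW212 tumours, it was 84, 99 and 21 for 4 h tumours 2, 3 and 5, 1298, 19 and 17 for 8 h tumours 2, 3 and 5, 14, 751, 5 and 847 for 24 h tumours 1, 2, 4 and 5, and 6, 1013 and 28 for 72 h tumours 3, 4 and 5. Among vehicle tumours it was 23, 458 and 26 for 4 h tumours 2, 3 and 5, 23, 25, 10 and 249 for 8 h tumours 1, 2, 4 and 5, 130, 26, 146 and 21 for 24 h tumours 1, 3, 4 and 5, and 27, 912 and 13 for 72 h tumours 3, 4 and 5. For B20.4.1 averaged, 34 of 40 tumours moved the count of 1, 21 of them to 0, and it was 14 without vehicle 24 h tumour 1 and 10 without vehicle 72 h tumour 4. For TW212 against B20.4.1 averaged 22 of 40 moved it, to 54 without TW212 8 h tumour 2 and to 9 without B20.4.1 4 h tumour 2, B20.4.1 8 h tumour 2, TW212 24 h tumour 5 or TW212 72 h tumour 1. For vehicle at 8 h it was 1 without 8 h tumour 3 or 4, and for vehicle at 72 h it was 82 and 159 without 4 h tumours 2 and 5 and 98, 161 and 105 without 72 h tumours 1, 3 and 4. For the B20.4.1 effect across times 16 of 40 moved it, to 7 without vehicle 72 h tumour 2.

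Of 84 named calls, 55 stayed past the threshold with no array set term, 74 with quantile normalization again and 15 in every leave-one-out, and none of these turned sign. Of 115 values from other probe sets of these genes, 5 stayed past the threshold, 91 did not pass and 19 turned sign. The values that turned sign were KANSL1L -0.0793 and SOCS3 -0.0444 for TW212 at 72 h, PPP3CA 0.137 for B20.4.1 at 4 h, ZNF451 -0.0659 and ANKRD37 0.0711 for B20.4.1 at 24 h, and RFX3 -0.0211, ITGB8 -0.0262, SOCS3 -0.0311 and PAXIP1-AS2 -0.0150 for B20.4.1 at 72 h. For TW212 averaged they were KANSL1L -0.0130 and -0.138, PAXIP1-AS2 -0.0980, EPB41L4A -0.0923, IGF1 0.0412, CDH11 0.000968 and PRSS23 0.0194. The others were EDRF1 -0.0498 for B20.4.1 averaged, PRSS23 0.0220 for TW212 against B20.4.1 averaged and ALOX5 0.00578 for vehicle at 72 h.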

Other observations

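Averaged over the 3 arms, the tumours of 72 h differed from those of 4 h in 236 genes, 194 higher and 42 lower. TFRC, the transferrin receptor, rose by 0.66 ± 0.07 on the log2 scale (SE, n = 15 tumours per time, adjusted p = 2.59e-08). CXCR4, a chemokine receptor, rose by 0.63 ± 0.10, IGFBP1, a binding protein of insulin-like growth factors, by 0.49 ± 0.07, and the glycolytic enzyme gene HK2 by 0.42 ± 0.08. The hydroxylase gene JMJD6 rose by 0.37 ± 0.05, CXCL8, a neutrophil chemokine, by 0.50 ± 0.12 and CCL2 by 0.50 ± 0.10. DPP4, a surface peptidase, fell by 0.26 ± 0.04 and LAMA2, a laminin chain, fell by 0.26 ± 0.05. Of the 236 genes, 91 were among the 256 of the vehicle tumours, which the share of these tumours in the average favours by design. The genes named here were chosen after their values were seen.

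Unfolded protein and integrated stress response genes had a median of 0.13 in that change, with 28 of 32 higher, 12 that rose over all genes and 22 that rose adjusted over the list alone (camera adjusted p = 8.15e-21, and adjusted p = 0.00239 with an estimated correlation, over 26 lists). Heat shock response genes had a median of 0.09, with the chaperone gene DNAJB1 at 0.28 ± 0.05, 4 of 18 that rose over all genes and 8 adjusted over the list alone (camera adjusted p = 1.77e-09, and adjusted p = 0.00987 with an estimated correlation). In the antibody arms alone CHORDC1 rose by 0.47 ± 0.07, HSPH1 by 0.38 ± 0.06 and DNAJB1 by 0.36 ± 0.07, with 6 of 18 heat shock genes that rose over all genes, and 11 that rose and 1 that fell adjusted over the list alone (camera adjusted p = 4.03e-16, and adjusted p = 0.000345 with an estimated correlation). In the vehicle tumours the heat shock median was -0.05, with 7 of 18 higher, CHORDC1 at -0.28 ± 0.10 and HSPH1 at -0.19 ± 0.09, neither past the threshold, and with 1 that rose over all genes, and 1 that rose and 1 that fell adjusted over the list alone (camera adjusted p = 0.414, and adjusted p = 0.727 with an estimated correlation). For vehicle minus antibody arms the heat shock median was -0.20, with 3 that fell over all genes, and 7 that fell and 2 that rose adjusted over the list alone (camera adjusted p = 1.18e-07, and adjusted p = 0.0422 with an estimated correlation). NF-kB target genes had a median of 0.09 over the 3 arms, with 5 of 41 that rose over all genes and 10 adjusted over the list alone (camera adjusted p = 3.70e-07, and adjusted p = 0.0175 with an estimated correlation). In the antibody arms alone the NF-kB median was 0.04, with 0 of 41 past over all genes, and 5 that rose and 1 that fell adjusted over the list alone (camera adjusted p = 0.00645, and adjusted p = 0.322 with an estimated correlation). In the vehicle tumours it was 0.15 (camera with an estimated correlation, adjusted p = 0.0663). Adjusted over the 78 time tests, as in the results above, the same vehicle test had an adjusted p = 0.199. Genes of the TWEAK receptor pathway had a median of 0.08 over the 3 arms, with 2 of 12 that rose over all genes and 2 adjusted over the list alone (camera adjusted p = 6.60e-05, and adjusted p = 0.0465 with an estimated correlation). Their median was 0.05 in the antibody arms alone and 0.16 in the vehicle tumours (camera with an estimated correlation, adjusted p = 0.424 and 0.0904). For vehicle minus antibody arms neither the NF-kB list nor this list passed camera with an estimated correlation (adjusted p = 0.556 each). The NF-kB and TWEAK receptor lists share members, TNFAIP3 among them, and are not independent. The other list p-values of this paragraph were adjusted over the 26 lists within each change, and not over the changes together. That family is smaller than those used in the results above. Whether the lists that passed here would pass over a larger family was not tested.

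Of the 256 vehicle genes, 188 had the same sign in the antibody arms, where the median change was 0.124 of that in vehicle tumours. These genes were chosen for their change in the same vehicle tumours, which favours a small share by design. For 52 genes chosen in other vehicle tumours than those that gave the vehicle change, 2 per time, the share was 0.362. Of 35 genes that passed in the antibody arms 4 were among the 256, and the changes of the vehicle and antibody arms had a correlation of 0.112 across genes, which are not independent replicates. The covariance of the TW212 and B20.4.1 effects averaged over time was 0.00259, within the range of -0.000133 to 0.00304 (mean 0.00112) of simulated unchanged groups. Those draws simulated the vehicle groups too. The repeat array of vehicle 24 h tumour 2 lay nearer to an array of TW212 at 8 h (0.194) than to its own first array (0.202).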
